A study of Rattus norvegicus with 6 samples.

How the data were processed

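RNA abundance was measured with 6 Affymetrix Rat 230 2.0 arrays, each hybridised with biotin-labelled cRNA from 1 preparation of rat renal inner medulla. Per the labels' protocols, male Sprague-Dawley rats received 1 mg of the loop diuretic furosemide into the peritoneum 30 min before they were killed, and the excised tissue was digested for 75 min at 37 °C with collagenase B and hyaluronidase. Low-speed centrifugation gave a fraction enriched in inner medullary collecting duct cells, called IMCD here. The cells left in the supernatant formed the other fraction, called nonIMCD. Per the labels, 7 rats were used, about 3 µg of total RNA went onto each array, and the isolation was done 3 times. How the rats were spread over the arrays is not given in the sources used here. The study's text speaks of 3 pairs of fractions, the nonIMCD fraction coming from the supernatant of the IMCD fraction. By that text the 6 preparations are not independent, but which arrays form a pair is not given. The main fit took no account of pairs, and its p-values measure the spread between the arrays of a fraction. The age label reads 6 weeks for IMCD replicate 1 and 10 weeks for the other 5 arrays.

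The deposited values are intensities on a linear scale, 1 per probe set and array. They had been scaled by the authors: the mean of the middle intensities, with 2% trimmed at each end, was 1000.3 to 1000.4 on each of the 6 arrays. The software and settings that made them are not given in the sources used here. Detection calls were not used here. Scaling every array to 1 trimmed mean fixes the average brightness, so a difference means a change relative to that average. All 6 columns of values were matched to samples.

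The table held 31099 probe sets. The 57 control probe sets were left out of the tests and 31042 were tested. Gene names came from the platform annotation of 2016, updated through the gene identifiers of the RefSeq annotation of the GRCr8 assembly, from which no coordinates were used. In that annotation 20826 tested probe sets had 1 gene symbol, 436 had several and 9780 had none, and 20764 of the single symbols were found by identifier, with 0 symbols changed. No gene was named from a probe set with several symbols. For counts of genes and for gene lists, each of 14217 genes was represented by its probe set with the highest mean log2 value over all 6 arrays.

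Intensities were analysed as log2(value + 16), a scale that understates differences between dim signals. No filter on low values was applied. The fractions were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, all 6 arrays, no covariate). P-values were adjusted by the Benjamini-Hochberg method over all 31042 probe sets, and an adjusted p under 0.05 counted as past the threshold. Differences are IMCD minus nonIMCD, errors of log2 differences are standard errors (SE) from the fit, and errors of intensities are SD over 3 arrays. Array number limits the precision.

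The comparison, its test, the alternatives, the rule for naming genes and 24 gene lists were chosen before the data were examined. The lists covered cell types of the inner medulla and its surroundings (collecting duct principal cell, intercalated cell, thin limb of Henle, thick ascending limb, proximal tubule, distal convoluted tubule, endothelial cell, interstitial cell and pericyte, leukocyte, erythroid, urothelium). They also covered tight junctions, epithelial adhesion and keratins, osmolyte and hypertonicity response, vasopressin and cAMP signaling, endothelin with prostaglandin, nitric oxide and natriuretic peptide genes, purinergic and kinin receptors, vesicle docking and apical trafficking, ion and solute transport of the collecting duct, glycolysis, oxidative phosphorylation with the citrate cycle, immediate early and dissociation response, cell cycle and housekeeping genes. Named genes were the 8 with the largest difference in each direction among genes past the threshold whose arrays did not overlap, all measured collecting duct principal cell genes, and up to 3 genes per other list with the largest difference past the threshold, or the largest 1 where none passed. Symbols made of LOC or RGD and a number were left out of the first part. Other genes named in the text are list or family members chosen after their values were seen.

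Lists were tested with limma's camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists. Camera compares a list with the other genes. It was repeated with a correlation estimated from the data, and fry was run as a further test of whether a list's genes move, on balance, in 1 direction. Camera calls were made for 11 lists at the preset correlation, and 0 of these 11 calls held with an estimated correlation. Fry passed all 11 in the same direction. For the thin limb, epithelial adhesion and glycolysis lists the estimated correlation was -0.012, -0.0063 and -0.021. These values lie under the preset 0.01, so a higher correlation within these lists did not end their calls. RNA quality was described by log2 ratios of 3' to 5' control probe sets for 3 rat transcripts and 4 bacterial spike-in transcripts (8 probe set pairs), and the signal without target by 3 negative control probe sets, whose highest intensity on any array was 78.4. The level of the hybridisation controls was taken as their mean log2 intensity on each array.

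The test was checked on simulated data with the arrays' own means and spreads. With 200 of 31042 probe sets changed, 0.0% of those changed 1.5-fold, 8.0% changed 2-fold, 56.0% changed 4-fold and 64.0% changed 8-fold were recovered, and 4 of 68 calls were false. With 6000 changed 4-fold, 86.4% were recovered and 4.55% of calls were false. With 1 of the 24 lists lowered, camera called that list and 0 of the others. The simulated noise was independent between probe sets, so these checks do not cover correlation between genes. In the real lists the estimated correlation ran from -0.05 (distal convoluted tubule) to 0.77 (erythroid).

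The alternatives were the replicate number as a block, quantile normalization, centring each array on its median, pseudocounts of 1 and 64, only probe sets above the median mean, an intensity trend with robust variances, array weights, leaving out each array and each pair of equal number, limma's treat against a 1.5-fold difference, an adjusted p under 0.01, the mean of a gene's probe sets, and the further list tests. Figures were drawn with matplotlib 3.10.9.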

Results

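Gene expression was profiled in 2 fractions of the digested rat inner medulla, the innermost part of the kidney. The IMCD fraction was enriched in cells of the inner medullary collecting duct, the last tubule segment that urine passes and the site where vasopressin regulates water and urea permeability. The nonIMCD fraction held the cells that stayed in the supernatant. Each fraction was measured on 3 arrays. The median deposited intensity of a probe set was 270.3 to 273 on the IMCD arrays and 330.1 to 341 on the nonIMCD arrays. Across probe sets, log2 values correlated at r = 0.956 to 0.967 between arrays of 1 fraction and at r = 0.901 to 0.911 between fractions. The first principal component held 58.1% of the variance and separated the fractions. The median SD between arrays of a fraction was 0.28 on the log2 scale, and 0.18 for probe sets with a mean log2 value above 8.

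Control transcripts differed between the fractions in their 3' to 5' signal, a measure of RNA integrity and labelling length. The log2 ratio averaged over Actb, Gapdh and hexokinase was 0.69 ± 0.03 (SD, n = 3) on the IMCD arrays and 1.35 ± 0.14 (SD, n = 3) on the nonIMCD arrays. For Actb the 3' probe set was 1.83 times as bright as the 5' probe set in IMCD and 2.86 times as bright in nonIMCD. For hexokinase these ratios were 2.19 and 4.54, and for Gapdh 1.05 and 1.31. Bacterial control transcripts averaged 0.69 ± 0.07 and 0.83 ± 0.11 (SD, n = 3). Their probe set pairs divided: 1 set of 4 was higher in nonIMCD by 0.20 to 0.39, and the other set for the same 4 transcripts differed by -0.22 to 0.16. This shift in the rat transcripts went with every fraction difference given in the paragraphs that follow. The hybridisation controls had a mean log2 intensity of 12.32 ± 0.11 on the IMCD arrays and 12.62 ± 0.33 on the nonIMCD arrays (SD, n = 3).

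**Figure D1:**
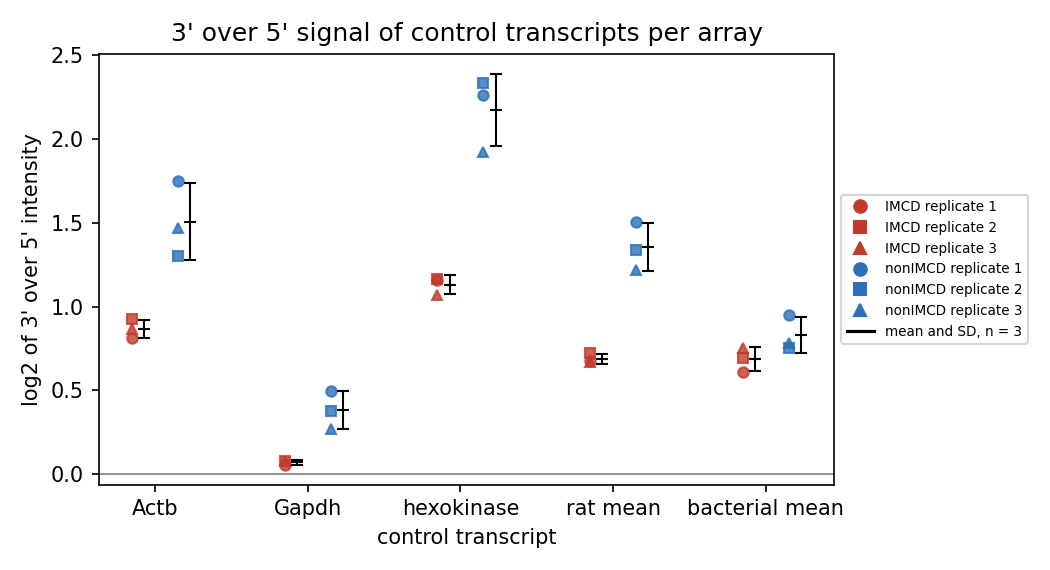
Log2 of the 3' over 5' intensity (vertical axis) of 3 rat control transcripts, their mean and the mean of the bacterial controls (horizontal axis) on each array, with mean and SD of 3 arrays per fraction. The rat mean was 0.67 to 0.72 on the IMCD arrays and 1.22 to 1.503 on the nonIMCD arrays.

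The comparison asked which transcripts distinguish collecting duct cells from the other cells of the inner medulla. Of 18 measured collecting duct principal cell genes 14 were higher in the IMCD fraction, with a median log2 difference of 1.22 over the list. Among those with the largest differences, the transcription factor Elf5, the vasopressin receptor Avpr2 and the sodium channel subunit Scnn1g were 4.05 to 5.90 times as bright there. Transcripts of thin limbs, blood vessels and leukocytes were lower there, among them the water channel Aqp1 by 11.2-fold, von Willebrand factor (Vwf) by 17.9-fold, and the complement subunit C1qb, whose IMCD mean lay under the highest negative control. In limma's test 2663 probe sets were higher and 4163 lower in IMCD, and 1316 and 2619 of these differed at least 2-fold. These correspond to 1427 higher and 2239 lower genes, of which 654 and 1401 differed at least 2-fold. The IMCD and nonIMCD arrays did not overlap for 13098 probe sets (42.2%), against 10% by chance. Among 716 called genes with at least 2 called probe sets, 13 had probe sets called in opposite directions.

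The balance of directions rested on the scaling. Higher calls made up 39.0% of calls with the deposited scaling, 67.0% (5389 higher, 2652 lower) with each array centred on its median and 52.1% (3443 higher, 3171 lower) after quantile normalization. The median difference of all probe sets was -0.10 as deposited, and it moved up by 0.29 and 0.15 on the log2 scale under these scalings. Without 1 array, the count of higher probe sets fell to 1537, 1717 and 1725 (IMCD replicates 1, 2 and 3) and to 1666 with 2647 lower (nonIMCD replicate 1).

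The genes with the largest excess in IMCD included secreted signals and a transporter. Ccl20, a chemokine, differed by 3.57 ± 0.40 on the log2 scale (SE, adjusted p = 0.00257), with intensities of 4399 ± 615 in IMCD and 393 ± 237 in nonIMCD (SD, n = 3). The cytokine Il6 differed by 3.26 ± 0.50 (adjusted p = 0.00793), with a wide spread in IMCD (3555 ± 2417, SD, n = 3). Slc9a4, a sodium-hydrogen exchanger, differed by 3.24 ± 0.22 (adjusted p = 0.000581). The cornified envelope gene Sprr1a (3.43), the lectin Reg3b (3.08) and the open reading frame C9h6orf141 (3.06) were also among them. Serpina11 (3.62) and the adrenergic receptor Adra1d (3.56) had nonIMCD intensities of 36.6 and 42.1, within the range of the negative controls, so their size depends on the pseudocount.

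The 8 genes with the largest deficit in IMCD are known from leukocytes. The chemokine Ccl6 differed by -7.84 ± 0.21 (SE, adjusted p = 0.000117), with 9.13 ± 5.84 in IMCD and 5680 ± 773 in nonIMCD (SD, n = 3). Rgs1, a regulator of G protein signaling, Cybb, the NADPH oxidase subunit of phagocytes, and the tetraspanin Cd53 differed by -6.37, -6.15 and -6.07. C1qb (-7.06), Aif1 (-6.79), the integrin Itgax (-6.52) and granzyme B (Gzmb, -6.03) completed the group. In IMCD, Ccl6, C1qb, Aif1, Itgax and Gzmb lay at or under the highest negative control, which makes their size and order uncertain. A second, dim probe set of Aif1 gave 0.51 (adjusted p = 0.558), and the brighter one is of a type that can match several transcripts.

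Collecting duct principal cell genes were higher in IMCD. Of 18 measured members 14 were higher, 0 were lower and 4 did not pass, with 14 higher when adjusted over the list alone and a median difference of 1.22. The largest differences were those of Elf5 (2.56 ± 0.15, SE, adjusted p = 0.000412), Scnn1g (2.48 ± 0.19, adjusted p = 0.000878), the transcription factor Gata3 (2.15 ± 0.26, adjusted p = 0.00346) and Avpr2 (2.02 ± 0.12, adjusted p = 0.000493). Elf5 had an intensity of 7041 ± 98.4 in IMCD and 1187 ± 166 in nonIMCD (SD, n = 3). Hsd11b2, which protects the mineralocorticoid receptor from glucocorticoids, differed by 1.87 and that receptor's gene Nr3c2 by 1.03. The sodium channel subunits Scnn1b and Scnn1a (1.67 and 1.24), the transcription factors Gata2, Tfcp2l1 and Hoxb7 (1.55, 1.39 and 0.94) and the sodium pump regulator Fxyd4 (0.84) were also higher.

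Among water and urea channels, basolateral Aqp3 and Aqp4 were higher, by 1.21 ± 0.16 (SE, adjusted p = 0.00484) and 1.17 ± 0.18 (adjusted p = 0.00762). The apical water channel Aqp2 had 52570 ± 4261 in IMCD and 43300 ± 6559 in nonIMCD (SD, n = 3), a difference of 0.29 ± 0.16 that did not pass (adjusted p = 0.261). It passed under median centring (0.58, adjusted p = 0.0403) and quantile normalization (0.45, adjusted p = 0.0406). These intensities were near the top of the scale, where the brightest probe set of an array reached 70016 to 111657. The urea transporter Slc14a2 differed by 0.33 in its brightest probe set (adjusted p = 0.191), which can match several transcripts. That probe set had adjusted p = 0.0299 under median centring and adjusted p = 0.0816 after quantile normalization. The dimmer Slc14a2 probe sets gave 1.57 (adjusted p = 0.0142), 1.02 (adjusted p = 0.00403), 1.504 (adjusted p = 0.00367) and -0.25 (adjusted p = 0.857). Of these, the probe set at 1.02 is also of a type that can match several transcripts. For Aqp4 the dimmer probe sets gave 2.92 and 0.83, for Avpr2 0.67 and for Gata2 -0.02. Calca (-0.48, adjusted p = 0.607) and Kcne1 (0.31, adjusted p = 0.255) lay near the negative controls. For Kcne1 adjusted p was 0.0494 under median centring and 0.191 after quantile normalization. Dimmer Calca probe sets, under the highest negative control in both fractions, gave -1.04 (adjusted p = 0.0241) and -0.14 (adjusted p = 0.54).

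By camera the principal cell list was higher (adjusted p = 1.25e-09), with adjusted p = 0.13 with an estimated correlation. Hoxb7 lost its call without IMCD replicate 1 (0.96, adjusted p = 0.0561), IMCD replicate 2 (0.90, 0.0584), nonIMCD replicate 1 (0.82, 0.0523) or nonIMCD replicate 2 (0.90, 0.0582), Scnn1a without IMCD replicate 2 (1.23, 0.0509) or 3 (1.16, 0.0531), and Fxyd4 without nonIMCD replicate 1 (0.76, 0.0515).

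**Figure D2:**
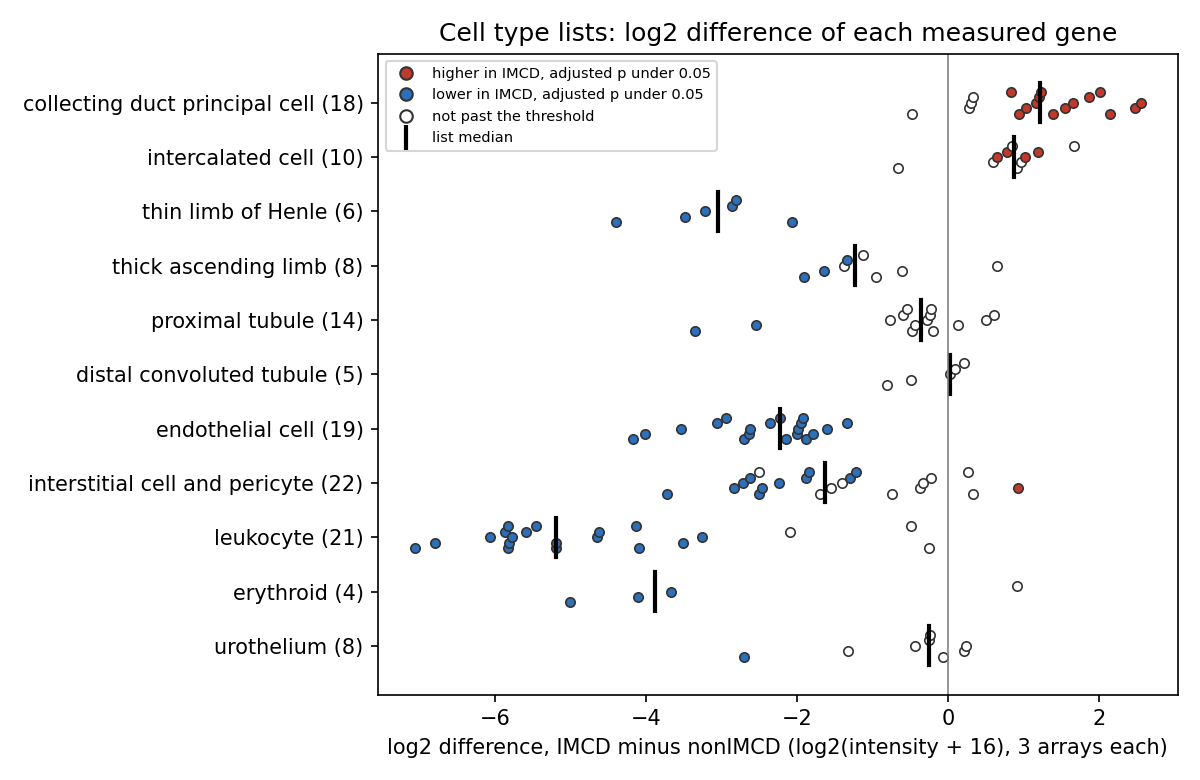
Log2 difference between IMCD and nonIMCD (horizontal axis) of each measured member of the cell type lists (vertical axis, number measured in brackets), with filled points past an adjusted p of 0.05 and bars at list medians. The medians ran from -5.19 for leukocyte genes to 1.22 for principal cell genes. The urothelium median of -0.24 turned to 0.04 under median centring and 0.01 after quantile normalization.

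Intercalated cells, the acid-base transporting cells of the duct, left 4 of 10 measured genes higher, 0 lower and 6 not passing, and 5 higher with 1 lower when adjusted over the list alone. The proton pump subunit Atp6v0a4 (1.20 ± 0.21, SE, adjusted p = 0.0122), the transcription factor Foxi1 (1.03 ± 0.21, adjusted p = 0.0213) and the carbonic anhydrase Car2 (0.78 ± 0.13, adjusted p = 0.00989) were higher. The bicarbonate exchanger Slc26a4 had -0.66 (adjusted p = 0.0832). The list median was 0.88 (camera adjusted p = 0.00285, and adjusted p = 0.356 with an estimated correlation). Foxi1 lost its call without IMCD replicate 1 (0.96, adjusted p = 0.0738), IMCD replicate 3 (0.90, 0.0618), nonIMCD replicate 1 (0.94, 0.0718) or nonIMCD replicate 2 (1.05, 0.0628).

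Thin limbs of Henle, which run beside the collecting ducts, showed the opposite direction. All 6 measured genes were lower in IMCD, also when adjusted over the list alone, with a median of -3.04. Aqp1 had 5698 ± 1349 in IMCD and 63190 ± 10350 in nonIMCD (SD, n = 3), a difference of -3.48 ± 0.24 (SE, adjusted p = 0.000584). Bst1 differed by -4.39 ± 0.16 (adjusted p = 0.000204), and the ephrin receptor Epha7 by -3.22 ± 0.20 (adjusted p = 0.000526) with an IMCD level within the negative controls. Camera gave adjusted p = 3.19e-05, and adjusted p = 0.0692 with an estimated correlation.

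Of 8 thick ascending limb genes 3 were lower, 0 higher and 5 did not pass, also when adjusted over the list alone. The lower genes were the prostaglandin receptor Ptger3 (-1.90 ± 0.18, SE, adjusted p = 0.00164) and the claudins Cldn19 (-1.64 ± 0.16, adjusted p = 0.00164) and Cldn16 (-1.33 ± 0.13, adjusted p = 0.00165). The furosemide target Slc12a1 (-1.37, adjusted p = 0.261), Umod (-1.12, adjusted p = 0.278) and Egf (-0.95, adjusted p = 0.274) did not pass. The mean log2 value of the list was 7.90 on IMCD replicate 1, against 8.75 and 8.98 on IMCD replicates 2 and 3 and 9.25 to 9.76 on the nonIMCD arrays. Camera gave a median of -1.22 and adjusted p = 0.038, and adjusted p = 0.343 with an estimated correlation. The call was lost without IMCD replicate 1 (-0.57, adjusted p = 0.0664), nonIMCD replicate 2 (-1.06, 0.0646) or nonIMCD replicate 3 (-1.12, 0.0855), with dim probe sets left out (-1.37, 0.0565) and with an intensity trend (0.051).

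Segments of the cortex gave few calls. Of 14 proximal tubule genes 2 were lower, 0 higher and 12 did not pass, also when adjusted over the list alone (median -0.35, camera adjusted p = 0.29, fry adjusted p = 0.00297). The endocytic receptor Lrp2 differed by -3.34 ± 0.19 (SE, adjusted p = 0.000425) and Gatm, an enzyme of creatine synthesis, by -2.54 ± 0.16 (adjusted p = 0.000493), with a dimmer Gatm probe set at -0.54 (adjusted p = 0.252). Of 5 distal convoluted tubule genes limma called 0 over all probe sets, 0 adjusted over the list alone and 0 at an unadjusted p under 0.05. The largest difference there was that of Klk1 (-0.80, adjusted p = 0.277), near the negative controls. For that list the median was 0.03, the mean -0.19, camera's direction up (adjusted p = 0.971) and fry's direction down.

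Endothelial genes were lower in IMCD throughout the list. All 19 measured members were lower, also when adjusted over the list alone, with a median of -2.22. Vwf had 158 ± 53.2 in IMCD and 3008 ± 307 in nonIMCD (SD, n = 3), a difference of -4.16 ± 0.26 (SE, adjusted p = 0.000526). The urea transporter of descending vasa recta, Slc14a1, differed by -4.01 ± 0.23 (adjusted p = 0.000399), and the endothelial claudin Cldn5 by -3.53 ± 0.20 (adjusted p = 0.000399). Camera gave adjusted p = 3.17e-13, and adjusted p = 0.0692 with an estimated correlation.

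Of 22 interstitial cell and pericyte genes 11 were lower, 1 was higher and 10 did not pass, with 15 lower and 1 higher when adjusted over the list alone. The intermediate filament Vim differed by -3.72 ± 0.13 (SE, adjusted p = 0.000202), the collagen Col3a1 by -2.83 ± 0.16 (adjusted p = 0.000399) and the matrix protein Sparc by -2.71 ± 0.16 (adjusted p = 0.000426). The calcium-binding gene S100a4 was higher (0.93, adjusted p = 0.00989). Lum (0.27, adjusted p = 0.832) and Acta2 (0.33, adjusted p = 0.226) did not pass. The median was -1.62 (camera adjusted p = 0.000551, and adjusted p = 0.0794 with an estimated correlation), and 9 and 8 members were lower, and 2 and 1 higher, under median centring and quantile normalization.

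Leukocyte genes gave the largest list difference, a median of -5.19. Of 21 members 18 were lower, 0 higher and 3 did not pass, also when adjusted over the list alone. C1qb and Aif1, both expressed by macrophages, and Cd53, found on most leukocytes, differed by -7.06 ± 0.46, -6.79 ± 0.47 and -6.07 ± 0.39 (SE, adjusted p = 0.000531, 0.000612 and 0.000531). The pattern receptor Cd14 had 6432 ± 488 in IMCD and 7649 ± 776 in nonIMCD (SD, n = 3) and did not pass (-0.25, adjusted p = 0.264). Cd163 (-0.49, adjusted p = 0.471) and the T cell gene Cd3e (-2.09, adjusted p = 0.149) did not pass either. Camera gave adjusted p = 3.17e-13, and adjusted p = 0.0716 with an estimated correlation.

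Of 4 erythroid genes 3 were lower, 0 higher and 1 did not pass, also when adjusted over the list alone. Hemoglobin beta (Hbb), whose probe set can match related globins, was lower in every IMCD array (650 to 2848) than in any nonIMCD array (28650 to 80470), a difference of -5.01 ± 0.67 (SE, adjusted p = 0.00475). The heme enzyme Alas2 differed by -4.10 ± 0.69 (adjusted p = 0.0107) and the globin chaperone Ahsp by -3.67 ± 0.72 (adjusted p = 0.0184), with Ahsp near the negative controls in IMCD. Slc4a1, also on the intercalated cell list, had 0.91 (adjusted p = 0.165). The list median was -3.88 (camera adjusted p = 0.233, fry adjusted p = 0.0256). The arrays numbered 1 had the lowest Hbb in both fractions, and Ahsp lost its call without IMCD replicate 1 (-3.45, adjusted p = 0.0645), IMCD replicate 2 (-3.60, 0.0588) or nonIMCD replicate 2 (-3.69, 0.0605).

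**Figure D3:**
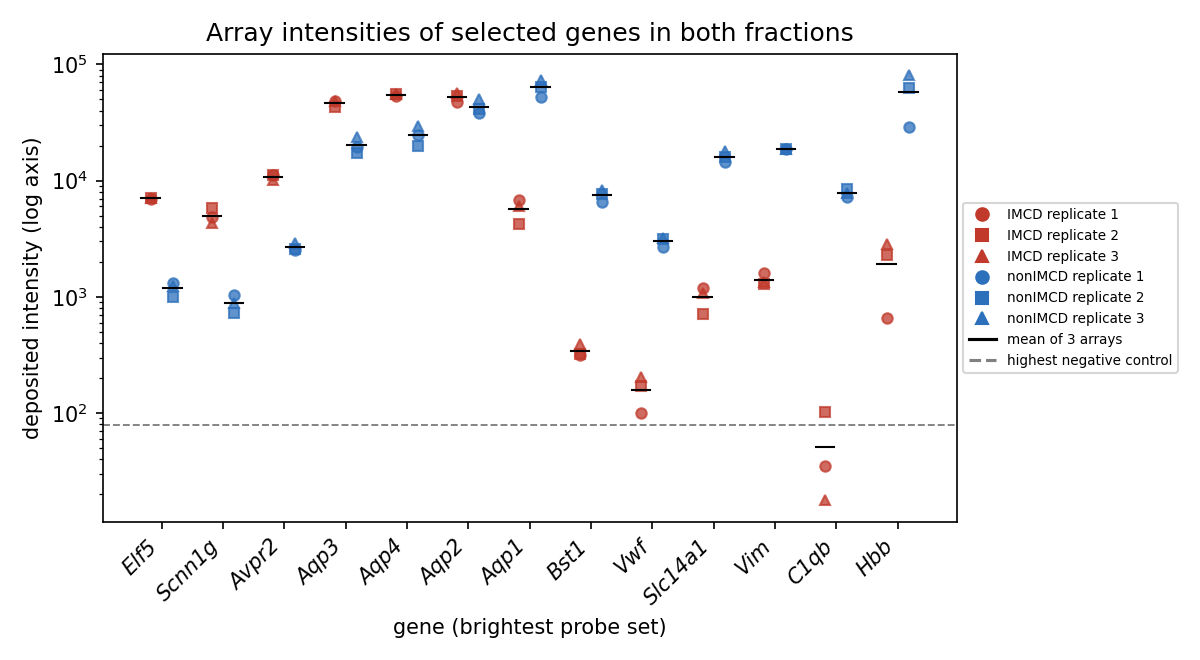
Deposited intensity on a log axis (vertical) of 13 genes (horizontal axis) on each of 6 arrays, with bars at the means of 3 arrays and a dashed line at the highest negative control, 78.4. Elf5 lay at 7041 in IMCD and 1187 in nonIMCD, Aqp2 at 52570 and 43300, and Hbb at 1927 and 57390.

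Of 8 urothelial genes 1 was lower, 0 were higher and 7 did not pass, also when adjusted over the list alone. The lower gene was Trim29 (-2.70 ± 0.22, SE, adjusted p = 0.00103). The uroplakins Upk1a (-1.32, adjusted p = 0.126) and Upk3a (-0.25, adjusted p = 0.656) did not pass. The median was -0.24 (camera adjusted p = 0.436, fry adjusted p = 0.0166), and it was 0.04 and 0.01 under median centring and quantile normalization.

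Tight junction genes divided in direction. Of 25 members 8 were higher, 9 lower and 8 did not pass, with 10 higher and 9 lower when adjusted over the list alone. The higher members included Cldn7 (0.87, adjusted p = 0.00658), Cldn8 (0.86, adjusted p = 0.015), both known from the collecting duct, and occludin (Ocln, 1.39, adjusted p = 0.0018). The lower members included Cldn5 of endothelium, Cldn2 of leaky epithelia (-2.86 ± 0.40, SE, adjusted p = 0.00574, near the negative controls in IMCD) and Cldn11 (-2.49 ± 0.20, adjusted p = 0.000981). The median was 0.40 and the mean -0.32, camera's direction was up (adjusted p = 0.677) and fry's was down (adjusted p = 0.00538). Camera's direction turned to down under median centring (10 higher, 7 lower) and quantile normalization (9 higher, 8 lower).

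Epithelial adhesion and keratin genes were higher, with 8 of 20 higher, 1 lower and 11 not passing, and with 9 higher and 1 lower when adjusted over the list alone. The splicing regulator Esrp1 (1.93 ± 0.13, SE, adjusted p = 0.000543), the transcription factor Elf3 (1.77 ± 0.13, adjusted p = 0.00077) and the keratin Krt19 (1.67 ± 0.16, adjusted p = 0.00178) led. Keratin 7 (Krt7) was lower (-1.55, adjusted p = 0.00192). Epcam, a general epithelial marker, had 0.26 (adjusted p = 0.25). The median was 0.36 (camera adjusted p = 0.000177, and adjusted p = 0.0692 with an estimated correlation), and 14 and 10 members were higher under median centring and quantile normalization.

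Vasopressin and cAMP signaling genes changed in both directions, 5 of 25 higher, 5 lower and 15 not passing, with 7 higher and 5 lower when adjusted over the list alone and 9 higher and 4 lower under median centring. The calmodulin-dependent phosphodiesterase Pde1a was higher by 3.04 ± 0.30 (SE, adjusted p = 0.0018), beside Avpr2. The vascular vasopressin receptor Avpr1a was lower (-3.13 ± 0.12, adjusted p = 0.000204), as was the kinase anchor Akap12 (-2.32 ± 0.21, adjusted p = 0.00151). Adenylyl cyclase Adcy6 had 0.48 (adjusted p = 0.105). The median was 0.17, the mean -0.03, camera's direction up (adjusted p = 0.369) and fry's down.

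In the endothelin, prostaglandin, nitric oxide and natriuretic peptide list 5 of 23 genes were higher, 11 lower and 7 did not pass, with 5 higher and 14 lower when adjusted over the list alone. The higher genes included the cyclooxygenases Ptgs2 (2.22, adjusted p = 0.00202) and Ptgs1 (1.68, adjusted p = 0.0015) and the prostaglandin synthases Ptges (2.25, adjusted p = 0.00149) and Ptgds (1.59, adjusted p = 0.00758). The synthases Ptges2 (0.30, adjusted p = 0.227) and Ptgis (-0.86, adjusted p = 0.443) did not pass. The prostaglandin transporter Slco2a1 (-3.65 ± 0.14, SE, adjusted p = 0.000204), the receptor Ptger2 (-3.01 ± 0.33, adjusted p = 0.00259, near the negative controls in IMCD) and endothelial nitric oxide synthase Nos3 (-2.70 ± 0.13, adjusted p = 0.000278) were lower. The median was -1.17 (camera adjusted p = 0.136, fry adjusted p = 0.000173), and camera passed under median centring (adjusted p = 0.00695).

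Purinergic and kinin receptor genes numbered 18, of which 3 were higher, 5 lower and 10 did not pass, with 3 higher and 7 lower when adjusted over the list alone. P2ry12, a receptor of platelets and microglia (-4.76 ± 0.53, SE, adjusted p = 0.00255), P2ry6 (-4.14 ± 0.68, adjusted p = 0.01) and the ectonucleotidase Entpd1 (-2.68 ± 0.45, adjusted p = 0.0109) were lower, with P2ry12 and Entpd1 near the negative controls in IMCD. Entpd2 (1.36, adjusted p = 0.00233), P2ry1 (1.47, adjusted p = 0.0342) and Adora1 (0.89, adjusted p = 0.00738) were higher. The median was -0.60 (camera adjusted p = 0.265, fry adjusted p = 0.0226).

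Vesicle docking and apical trafficking genes showed 6 of 24 higher, 2 lower and 16 not passing, with 6 higher and 4 lower when adjusted over the list alone. Sytl4, a synaptotagmin-like protein (1.38 ± 0.26, SE, adjusted p = 0.0164), Rab11fip5 (1.06 ± 0.13, adjusted p = 0.00354) and the epithelial GTPase Rab25 (1.03 ± 0.15, adjusted p = 0.00657) were higher. The motor Myo5b (-0.52, adjusted p = 0.0332) and Rab5c (-0.73, adjusted p = 0.0417) were lower, and under median centring 11 members were higher and 0 lower. The median was 0.12 (camera adjusted p = 0.13, fry adjusted p = 0.00409). Sytl4 lost its call without IMCD replicate 1 (1.35, adjusted p = 0.0582) or 3 (1.29, 0.0558).

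Ion and solute transport genes of the collecting duct numbered 22, of which 4 were higher, 5 lower and 13 did not pass, with 5 higher and 6 lower when adjusted over the list alone. The potassium channel Kcnq1 (1.90 ± 0.13, SE, adjusted p = 0.000603) and the cyclic nucleotide-gated channel Cnga1 (1.63 ± 0.26, adjusted p = 0.0085) were higher. Kcnj16, another potassium channel, was lower (-1.58 ± 0.25, adjusted p = 0.00827). The median was 0.22 (camera adjusted p = 0.29, fry adjusted p = 0.0104), with 7 members higher and 1 lower under median centring, and 4 and 3 after quantile normalization.

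Of 13 osmolyte and hypertonicity response genes 3 were higher, 2 lower and 8 did not pass, with 4 higher and 3 lower when adjusted over the list alone and 6 higher and 2 lower under median centring. The taurine transporter Slc6a6 (-2.90 ± 0.19, SE, adjusted p = 0.000531) and Nfat5, the transcription factor of the hypertonic response (-1.14 ± 0.11, adjusted p = 0.00181), were lower, and the kinase Sgk1 was higher (0.77 ± 0.11, adjusted p = 0.00721). Aldose reductase Akr1b1, which makes sorbitol, had -0.17 (adjusted p = 0.565). The median was 0.28 and the mean -0.08, with camera up (adjusted p = 0.29) and fry down.

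Glycolysis genes were higher, with 7 of 14 higher, 0 lower and 7 not passing, and 9 higher when adjusted over the list alone. Lactate dehydrogenase Ldha had 36150 ± 1071 in IMCD and 16830 ± 1456 in nonIMCD (SD, n = 3), a difference of 1.11 ± 0.12 (SE, adjusted p = 0.00275). Hexokinase Hk2 differed by 1.93 ± 0.40 (adjusted p = 0.0218) and Aldoc by 1.05 ± 0.19 (adjusted p = 0.0131). The median was 0.52 (camera adjusted p = 6.06e-05, and adjusted p = 0.0692 with an estimated correlation), and 10 and 6 members were higher under median centring and quantile normalization. Hk2 lost its call without IMCD replicate 1 (1.71, adjusted p = 0.0695), IMCD replicate 3 (1.96, 0.0618) or nonIMCD replicate 1 (1.95, 0.0673).

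Of 30 oxidative phosphorylation and citrate cycle genes 3 were higher, 0 lower and 27 did not pass, also when adjusted over the list alone. The mitochondrial coactivator Ppargc1a differed by 0.88 ± 0.20 (SE, adjusted p = 0.0275), Sdhc by 0.60 ± 0.14 (adjusted p = 0.0281) and Ndufa4 by 0.54 ± 0.12 (adjusted p = 0.0243). The median was 0.27 (camera adjusted p = 1.11e-05, and adjusted p = 0.32 with an estimated correlation), and 22 members were higher under median centring but 2 after quantile normalization, which ended the calls of Sdhc (0.43, adjusted p = 0.0709) and Ndufa4 (0.37, 0.0707). All 3 lost their calls without any 1 of IMCD replicates 1, 2 and 3 or nonIMCD replicates 1 and 2, with differences of 0.73 to 0.97 for Ppargc1a, 0.54 to 0.64 for Sdhc and 0.50 to 0.57 for Ndufa4.

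Immediate early and dissociation response genes were bright in both fractions, and 2 of 23 were higher, 3 lower and 18 did not pass, also when adjusted over the list alone, with 5 higher and 3 lower under median centring. Fos (-0.19, adjusted p = 0.349), Egr1 (-0.01, adjusted p = 0.962) and Atf3 (0.24, adjusted p = 0.319) did not pass, with Egr1 at 43420 ± 2214 in IMCD and 43800 ± 3322 in nonIMCD (SD, n = 3). The matricellular gene Ccn2 (-3.06 ± 0.23, SE, adjusted p = 0.000803) and the flow-responsive endothelial factor Klf2 (-2.21 ± 0.18, adjusted p = 0.00104) were lower. Dimmer Klf2 probe sets gave -2.23, -1.05, -0.36 (adjusted p = 0.256) and -0.34 (adjusted p = 0.338). The AP-1 subunit Fosl1 was higher (2.03 ± 0.14, adjusted p = 0.00063). The median was 0.05 and the mean -0.18, camera's direction was up (adjusted p = 0.677) and fry's down, and the median was -0.07 after quantile normalization.

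Cell cycle genes were lower in IMCD, with 11 of 19 lower, 1 higher and 7 not passing, and 13 lower with 1 higher when adjusted over the list alone. The proliferation marker Mki67 differed by -2.41 ± 0.43 (SE, adjusted p = 0.0129), Plk1 by -1.74 ± 0.46 (adjusted p = 0.0467, near the negative controls in IMCD) and Cdk1 by -1.54 ± 0.34 (adjusted p = 0.0254). Thymidylate synthase Tyms was higher (0.57, adjusted p = 0.0401). The median was -0.89 (camera adjusted p = 0.00858, and adjusted p = 0.32 with an estimated correlation), and 5 and 2 members were lower under median centring and quantile normalization. Quantile normalization ended the calls of Plk1 (-1.46, adjusted p = 0.0847) and Cdk1 (-1.27, 0.0531), median centring that of Plk1 (-1.45, 0.0698), and leaving out any 1 array did so for Plk1 (-1.47 to -1.98) except IMCD replicate 1, and for Cdk1 (-1.27 to -1.56) except IMCD replicate 1 and nonIMCD replicate 1.

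Of 8 housekeeping genes 1 was lower, 0 higher and 7 did not pass, also when adjusted over the list alone, whereas 4 were higher and 0 lower under median centring, and 1 and 1 after quantile normalization. The ribosomal protein gene Rpl13a was lower (-0.53 ± 0.11, SE, adjusted p = 0.023), but not under median centring (-0.25, adjusted p = 0.172), nor without any 1 of the 6 arrays (-0.51 to -0.57). Tbp (0.36, adjusted p = 0.103) and B2m (-0.15, adjusted p = 0.544) did not pass. The median was 0.02 and the mean -0.0019, with camera up (adjusted p = 0.727, and down after quantile normalization) and fry down.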

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

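All alternatives for the counts, lists and named genes were planned; the check of the replicate numbers over brighter probe sets was added after the data were seen. Of 92 named genes 87 were past the threshold. Of these, 45 stayed past it in the same direction under every alternative run on them, 42 lost it under at least 1 and 0 turned in direction. Leaving out both arrays numbered 1, 2 or 3 ended 33, 32 and 21 of these calls, and no other alternative ended more than 10. Only 72 of the 87 were among the probe sets above the median mean, and treat and the stricter threshold were applied to counts alone. The calls shared with the deposited scaling numbered 5315 of 6826 under median centring and 5565 after quantile normalization, with 0 in the opposite direction. For probe sets near the negative controls, the signal over background limits the size of a difference. The causes of the changes below were not tested, except that fewer arrays, a stricter threshold or a minimum difference leave fewer calls by construction.

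With the replicate number as a block (a paired fit), 1831 probe sets were higher and 2993 lower, 1187 and 2298 of them at least 2-fold, and 4538 of the 6826 calls remained in the same direction. No list crossed the threshold under the block. Of the 87 named genes 9 did not pass in the paired fit (Hoxb7, Foxi1, Cnga1, Hk2, Sdhc, Ndufa4, Plk1, Cdk1 and Rpl13a). Same-numbered arrays deviated together at r = 0.040, 0.035 and 0.061 over all probe sets, against -0.036 to 0 for arrays of unlike number. The study's text speaks of 3 pairs without tying the numbers to them, and the ages given for the arrays numbered 1 differ (6 and 10 weeks). Each array correlated best with its own number, a hint of pairing from the data. Over 16673 brighter probe sets r was 0.135, 0.218 and 0.272, against at most 0.012 for arrays of unlike number.

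Median centring gave 5389 higher and 2652 lower probe sets, 2430 at least 2-fold higher, and turned camera's direction down for distal convoluted tubule (median 0.32) and tight junction genes (median 0.69). Quantile normalization turned camera's direction for tight junction (median 0.48), immediate early (median -0.0699) and housekeeping genes (median 0.027). With only probe sets above the median mean, 1372 were at least 2-fold lower and the thick ascending limb list missed the threshold (median -1.37, adjusted p = 0.0565), as it did with an intensity trend and robust variances (median -1.22, adjusted p = 0.051). Over its alternatives that list's adjusted p ran from 0.00252 to 0.343. Treat against 1.5-fold left 729 higher and 1585 lower probe sets, the same numbers at 2-fold or more, and an adjusted p under 0.01 left 1100 and 1912.

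With the mean of a gene's probe sets camera's direction turned for distal convoluted tubule genes (median -0.38), and the endothelin and prostaglandin (median -1.21) and vesicle docking lists (0.21) passed. An estimated correlation ended all 11 camera calls, those of principal cell (1.22), intercalated cell (0.88), thin limb (-3.04), thick ascending limb (-1.22), endothelial (-2.22), interstitial (-1.62) and leukocyte genes (-5.19), the values being medians, and of 4 lists beyond the cell types, 3 up and 1 down. Fry passed the 11 lists called by camera, in the same direction. Where camera did not, fry also passed for proximal tubule (median -0.35), erythroid (-3.88) and urothelium genes (-0.24). It did so too for 5 lists beyond the cell types, 2 up and 3 down. Fry's direction was opposite to camera's for distal convoluted tubule (median 0.033), tight junction (0.40, 1 of these 5), osmolyte (0.28), vasopressin (0.17), immediate early (0.053) and housekeeping genes (0.017).

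Leaving out arrays, singly or by number, gave 553 to 2248 higher and 1335 to 3221 lower probe sets, and 553 to 1433 and 1335 to 2491 at 2-fold or more. Higher counts moved by over 1.5 times without IMCD replicate 1 (1537), 2 (1717) or 3 (1725), nonIMCD replicate 1 (1666, with 2647 lower) or both arrays numbered 1 (553, with 1335 lower), 2 (811, with 1606 lower) or 3 (1230, with 2154 lower). The thick ascending limb median ran from -1.42 to -0.57, and its call was lost without IMCD replicate 1 (-0.57, adjusted p = 0.0664), nonIMCD replicate 2 (-1.06, adjusted p = 0.0646) or 3 (-1.12, adjusted p = 0.0855). That of erythroid genes ran from -4.60 to -3.23 (called without both arrays numbered 1, -4.38, adjusted p = 0.0351, with 0.0256 to 0.544 over the alternatives) and that of distal convoluted tubule genes from -0.30 to 0.00049. Camera's direction for distal convoluted tubule genes turned without IMCD replicate 1 (-0.15) or 3 (-0.063), nonIMCD replicate 1 (-0.18) or 3 (-0.24) or both arrays numbered 1 or 3. Immediate early genes ran from 0.011 to 0.12, and their direction turned without nonIMCD replicate 3 (0.018). Calca ran from -1.10 to 0.20, the latter without both arrays numbered 2.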

Other observations

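The gene families in this part, and all tests except that of the other array splits, were chosen after the data were seen; families were taken by symbol and tested as the lists were. Chemokine genes divided, with 7 of 29 higher in IMCD and 10 lower, and 9 and 9 under median centring. The higher ones included Ccl20, Ccl7 (2.04 ± 0.21, SE), Ccl28 (1.94), Cxcl11 (1.84) and Ccl2 (1.51), with Ccl2 at 20080 ± 3664 in IMCD and 7071 ± 1333 in nonIMCD (SD, n = 3). The lower ones included Ccl6, Ccl4 (-5.48), Ccl3 (-5.28), Xcl1 (-4.67) and Ccl5 (-3.90), with Ccl6 and Xcl1 near the negative controls in IMCD. Of 16 chemokine receptor genes 4 were lower, among them Cxcr4 (-4.85), and the scavenging receptor Ackr3 was higher (1.13). Cytotoxic lymphocyte genes were lower for 14 of 21 members, with perforin (Prf1) at -5.91 and granzyme A (Gzma) at -3.72, both near the negative controls in IMCD. All 4 class II histocompatibility genes were lower (-5.42 to -4.13), with RT1-Db1, at -5.42, near the negative controls in IMCD.

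Collagen genes were lower for 15 of 41 members and higher for 0, and semaphorin and plexin genes for 11 of 25 with 1 higher. Sema5a (-4.25), Sema3g (-3.67) and Plxnd1 (-2.62) were lower and Sema4a was higher (1.92, with 17140 ± 1977 in IMCD and 4498 ± 333 in nonIMCD, SD, n = 3). Among Rab GTPase genes 15 of 56 were higher and 5 lower (24 and 3 under median centring), led by Rab9b (2.67), Rab15 (2.46) and the epithelial Rab17 (1.81), with camera adjusted p = 0.00433 and adjusted p = 0.113 with an estimated correlation. Ribosomal protein genes were lower for 19 of 48 members with a median of -0.46 (camera adjusted p = 0.000104, and adjusted p = 0.499 with an estimated correlation). That median was -0.17 under median centring, where 1 member was lower and 1 higher, and -0.30 after quantile normalization, with 17 lower.

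Hox genes past the threshold went both ways, 8 of 22 higher and 7 lower. The HoxA members were lower in 5 of 5 cases, among them Hoxa9 (-3.18 ± 0.17, SE) and Hoxa10 (-2.64 ± 0.15), while 4 of 6 HoxB members, such as Hoxb6 (1.296 ± 0.114), and 4 of 7 HoxD members, such as Hoxd3 (2.22 ± 0.14), were higher. HoxC had 1 of 4 lower (Hoxc9, -3.45, near the negative controls in IMCD) and HoxD 1 lower (Hoxd10, -0.93). Under both other scalings 8 were higher and 6 lower. The hypothesis that the direction may follow the cluster was tested by Fisher's exact test of HoxA and HoxC against HoxB and HoxD, which gave p = 0.0014 over the 15 called genes; neighbouring genes of a cluster are not independent, and the same genes prompted the hypothesis, so it remains one.

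The real grouping of the 6 arrays gave 6826 calls, and the highest of the other splits gave 0. As 1 of 10 splits, the real grouping cannot reach a share under 0.05. Each of the other splits mixed arrays of both fractions, which puts the fraction difference into the spread within its groups. Their 0 calls therefore do not measure what chance gives. The excess of lower over higher calls was weighed as a product of scaling every array to 1 trimmed mean. For calls of any size this explanation stays open, since 67.0% of calls were higher under median centring. For calls of at least 8-fold, 398 lower stood against 22 higher as deposited. The counts were 298 against 37 under median centring and 336 against 27 after quantile normalization, a ratio of at least 8.05. These scalings moved the median difference by 0.29 and 0.15 on the log2 scale, little beside 8-fold. The counts therefore argue only against a scaling shift of about that size as the source of the 8-fold excess. No biological explanation was tested.

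The brightest probe sets of principal cell genes, those of Aqp4, Aqp2, Aqp3, Fxyd4 and Slc14a2, differed less than those of Elf5 or Scnn1g, although a dimmer Aqp4 probe set differed by 2.92. Carry-over of collecting duct cells into the nonIMCD fraction as the only cause would give all these genes 1 ratio if their probe sets responded alike. Compared were the 9 members with an IMCD mean under 13 on the log2 scale and both means above the negative controls. Their differences, from Hoxb7 (0.94) to Elf5 (2.56), had an SD of 0.581, which was 2.51 times their largest standard error (0.232). That error covers the spread between arrays but not unlike responses of probe sets. Among the 9, the probe sets of Scnn1g gave 2.48 and 2.34, those of Scnn1a 1.24 and 1.60, and those of Gata2 1.55 and -0.02. The second Gata2 probe set was dim (90.3 in IMCD and 98.4 in nonIMCD). The probe sets of Avpr2, which is not among the 9, gave 2.02 and 0.67. The values therefore do not decide, and carry-over stays open, as the only cause or a part of it. Compression of very bright signals could also narrow the differences, and the dimmer probe set differed more in 15 of 20 genes with a very bright probe set and in 424 of 695 (61.0%) of moderate brightness, with no minimum set on the difference, which Fisher's exact test did not separate (p = 0.249), so compression stays open. Expression of some members by other inner medullary cells was not tested.

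The higher 3' to 5' ratios of rat control transcripts on the nonIMCD arrays might come from weaker labelling of every transcript. The rat minus bacterial log2 ratio differed by 0.521 between the fractions, from a mean of 0.003 ± 0.079 in IMCD to 0.524 ± 0.078 in nonIMCD (SD, n = 3). That would weigh against weaker labelling only if such labelling raised the ratios of all transcripts alike, which was not tested. The rat transcripts themselves rose by unlike amounts, from 0.311 (Gapdh) to 1.041 (hexokinase). Transcript by transcript the values do not decide either. The bacterial probe set pairs changed by -0.223 to 0.390, which left the smallest rat rise at -0.079 relative to the largest bacterial one. Weaker labelling therefore stays open. Lower RNA integrity in the nonIMCD fraction, and a difference between cell types in transcript forms, stay open as well and were not tested.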
